A study of Mus musculus with 6 samples.

How the data were processed

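Gene expression was measured on Affymetrix Mouse Gene 2.0 ST arrays, single-colour oligonucleotide arrays read after biotin labelling, in Kupffer cells, the resident macrophages of the liver. The 6 arrays came from 3 mice, and each mouse gave one sample of monocyte-derived Kupffer cells (mKC) and one of embryonic Kupffer cells (eKC). Per the labels' protocols, both populations were sorted as cells positive for the leukocyte antigen CD45 and for a macrophage surface antigen, and negative for the integrin CD11b. The mKC gate was GFP-positive and tdTomato-negative, and the eKC gate was GFP-negative and tdTomato-positive. Each sample held 50000 cells, and 2 ng of total RNA per sample entered the labelling reaction, which amplifies RNA from small inputs. The mice had received a treatment that the labels abbreviate as sRBC without spelling it out. No untreated mice were analysed here, so no value below is a response to that treatment.

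The values analysed are the authors' processed table, 1 row per gene and 1 column per array. Per the submitters' processing notes the values were made with RMA, a method that corrects background, normalizes the arrays by quantiles and summarises the probes of each gene. The deposited values were taken as log2 intensities: they ran from 2.09 to 14.2, the range RMA gives on that scale, but the base of the logarithm, the software version and the probe definition are not given in the sources used here. The upper quartile of an array lay between 7.37 and 7.48 and the median between 5.21 and 5.28, so the arrays were already on a common scale. RMA compresses differences at low intensity, and the table carries no detection call, so a low value does not show that a gene was silent. For arrays, it is the number of animals that limits the precision.

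All 27835 rows carried an Ensembl mouse gene identifier, with 0 repeated. The table does not pair identifiers with gene symbols, and the reference table supplied for this work, with 49997 genes, held an Ensembl identifier for 0 of them. Therefore 0 rows could be given a symbol, and each row is called a feature below. The 38 gene lists fixed before the data were examined, the set tests planned on them and the planned check of the 4 genes of the sort and the reporter could not be run. The planned rule for named genes was to give the 15 largest differences in each direction among features past the threshold with the same sign in all 3 animals. The rule also left out predicted genes, clone names, microRNAs, small nucleolar RNAs and immunoglobulin or T cell receptor segments. That part needs symbols and could not be applied, so features chosen here may belong to those classes. The rest of the rule was kept, the 15 features of each direction are summarised, and the 2 largest of each direction are given by identifier. No coordinates are given because no genome position could be tied to a feature.

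The comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), as mKC minus eKC, on all 6 arrays, with the animal as a block, since the series' design text describes the samples as pairs from the same mice. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all 27835 features, and an adjusted p under 0.05 was the threshold. No low-intensity filter was applied. The fit had 2 residual degrees of freedom per feature, and limma's empirical Bayes step added 4.21 from the spread of all features. All errors given with a difference are limma's standard errors (SE), and those given with a group level are SD over 3 animals. The pairing comes from the animals themselves and not from the values: the deviations of an mKC array and an eKC array of the same animal from their group means correlated at -0.032, 0.026 and -0.019 over all features in animals 1, 2 and 3.

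The fit was tested on simulated data in 20 runs, each with 200 changed features among 27835 and the animals' own levels. With the spread of each feature drawn from limma's fitted prior, 98.0% of features changed by 2 on the log2 scale were recovered in the right direction, 70.4% of those changed by 1 and 1.25% of those changed by 0.5. False calls were then 4.74% of all calls. With the moderated spread of each feature used in its place, the recovery was 100%, 99.5% and 39.8%, and false calls were 11.3% of all calls, above the nominal 5% (0.05).

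The alternatives, fixed before the data were examined, were the fit without the block, the animal as a random effect, each animal left out in turn, quantile normalization, median centring, leaving out the lowest 30% or 50% of features by mean level, an intensity trend with robust estimation, array weights and other thresholds. An independent check of direction called features in 2 animals and read their sign in the third.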

Results

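Expression profiles were obtained from 6 arrays, 3 of monocyte-derived Kupffer cells (mKC) and 3 of embryonic Kupffer cells (eKC), with both populations sorted from the liver of each of 3 mice. Kupffer cells are the macrophages that line the liver sinusoids. Those of embryonic origin settle in the liver before birth, whereas monocyte-derived cells descend from circulating blood monocytes. In these mice, which carried a Cre recombinase under the control of CX3CR1 and a tdTomato reporter behind a floxed stop, the eKC gate was tdTomato-positive and the mKC gate was GFP-positive. The data comprised normalised log2 intensities for 27835 features, each an Ensembl mouse gene. Features could not be given gene symbols, so the genes that encode the sorting antigens and the Cre driver were not examined as a check of the labels.

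The arrays separated by sorted population. The first principal component held 45.2% of the variance and placed the 3 mKC arrays between -24.2 and -19.8 and the 3 eKC arrays between 20.8 and 23. Across features, Pearson correlations were 0.9937 to 0.9953 between mKC arrays and 0.9933 to 0.9951 between eKC arrays. Between an mKC and an eKC array they were lower, at 0.9892 to 0.9906 within an animal and 0.9891 to 0.9904 across animals. Features are not independent replicates, and these correlations describe only how alike the arrays were. The spread between animals was similar in both populations, with a median SD per feature of 0.117 in mKC and 0.120 in eKC (log2, n = 3). The second component and the third, with 17.2% and 15.6% of the variance, each set 1 array of animal 2 apart. Its eKC array scored 25.6 on the second component against -12.9 and -12.4 for the eKC arrays of animals 1 and 3. Its mKC array scored -24.5 on the third component against 10.8 and 13.2 for the other mKC arrays. The other array of animal 2 stood less far out on each, with 7.79 for mKC on the second component and 7.80 for eKC on the third. No array was a copy of another: of 27835 values, 26 to 41 were exactly identical in any 2 arrays, and any 2 arrays of one group differed by a median of 0.122 to 0.144 on the log2 scale.

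**Figure D1:**
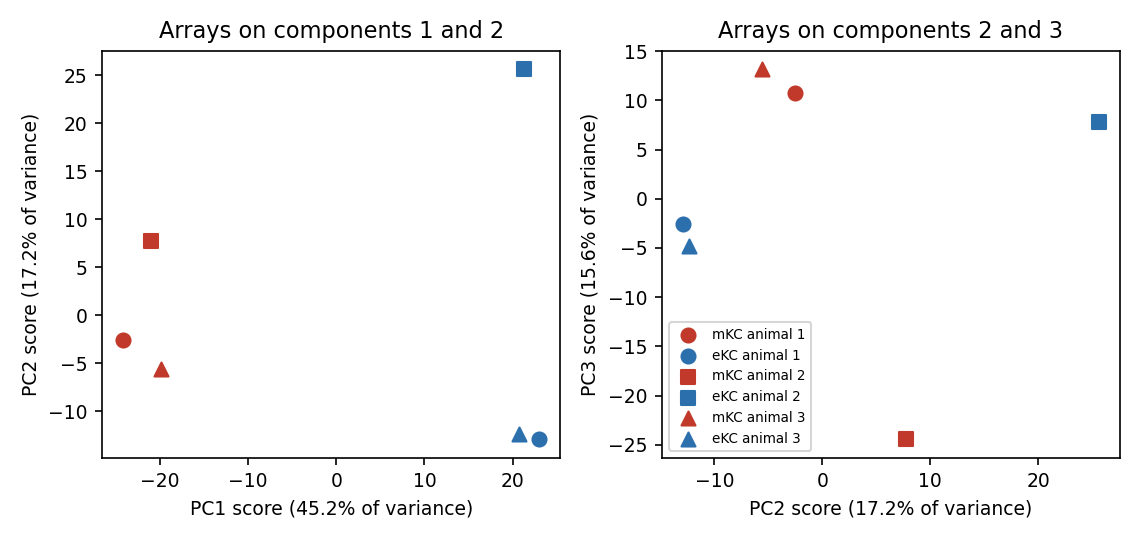
Scores of the 6 arrays on principal components 1 and 2 (left) and 2 and 3 (right), without units, with the share of variance on each axis; colour marks the cell group and the symbol marks the animal. The groups part on component 1. Of the arrays of animal 2 (squares), the eKC array stands apart on component 2 and the mKC array on component 3.

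The comparison of mKC with eKC addressed whether Kupffer cells assigned to different origins differ in gene expression within the same liver, in mice that had received the sRBC treatment. Origin was assigned by the sort gate, so a difference of origin cannot be told apart from other differences between the gated cells. Of 27835 features, 506 (1.82%) differed between mKC and eKC, of which 277 were higher in mKC and 229 were lower (limma, adjusted p under 0.05). In the simulations, false calls were 4.74% or 11.3% of all calls at this threshold, depending on the spread used. All 506 moved the same way in all 3 animals and 496 had groups that did not overlap, which a fit on 3 pairs favours in what it calls. Over all features, 33.0% moved the same way in all 3 animals, against 25% expected by chance, and 17.7% had groups that did not overlap, against 10% expected for 3 against 3. At an unadjusted p under 0.05, 3269 features differed, against 1392 expected by chance. Over all features, called or not, 5% of the differences lay below -0.297 and 5% above 0.324 on the log2 scale, and the median was -0.00793. The number of calls was lower with any 1 animal left out. It was 252 without animal 1, 369 without animal 2 and 171 without animal 3. Each of these fits had 1 residual degree of freedom in place of 2, which can lower the count by itself. The share of calls that were higher in mKC was 54.7% with all animals but 47.6%, 63.1% and 45.6% in the same order. Which direction held the majority of calls therefore changed with the animals included.

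Differences called from 2 animals mostly kept their direction in the animal that took no part in calling them. These lists differ from the 506 features called from all animals. With animals 1, 2 and 3 held out, 234, 291 and 158 of the features called were among the 506, so no list covered all of them. Of the 252 features called from animals 2 and 3, 246 (97.6%) had the same sign in animal 1, where 58.3% of all features did. Of the 369 called from animals 1 and 3, 357 (96.7%) had the same sign in animal 2, against 54.4% of all features. Of the 171 called from animals 1 and 2, 169 (98.8%) had the same sign in animal 3, against 56.3% of all features. The difference in the animal held out was a median of 94.7%, 79.0% and 98.8% of the difference in the other animals, for animals 1, 2 and 3.

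Of the called differences, 270 of 506 (53.4%) were below 2-fold. The smallest called difference, without its sign, was 0.531 on the log2 scale. In the simulations, 1.25% or 39.8% of changes of 0.5 were recovered, and 70.4% or 99.5% of changes of 1, depending on the spread used. The share below 2-fold and the medians that follow therefore depend on what the fit could detect. The median difference was 0.96 (1.94-fold) for features higher in mKC and -0.99 (1.98-fold) for features lower in mKC. A difference of at least 1 on the log2 scale was reached by 236 of the 506 features, 123 of them higher in mKC and 113 lower. Between 2 and 3 there were 10 features higher and 22 lower, and at 3 or above 5 higher and 10 lower. In all, 15 were higher and 32 lower by at least 2, but without animal 2 these counts were 26 and 31, and the imbalance itself was not tested. The 15 largest rises ran from 2.00 to 3.99 with a median of 2.41, and the 15 largest falls from -2.66 to -5.51 with a median of -3.52, each past the threshold (limma, adjusted p of at most 0.041 and 0.0033, SE of at most 0.320 and 0.251). Within single animals, 30, 21 and 20 features were higher in mKC by at least 2 in animals 1, 2 and 3, and 30, 38 and 36 were lower. Thus animal 1 showed as many large rises as large falls.

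**Figure D2:**
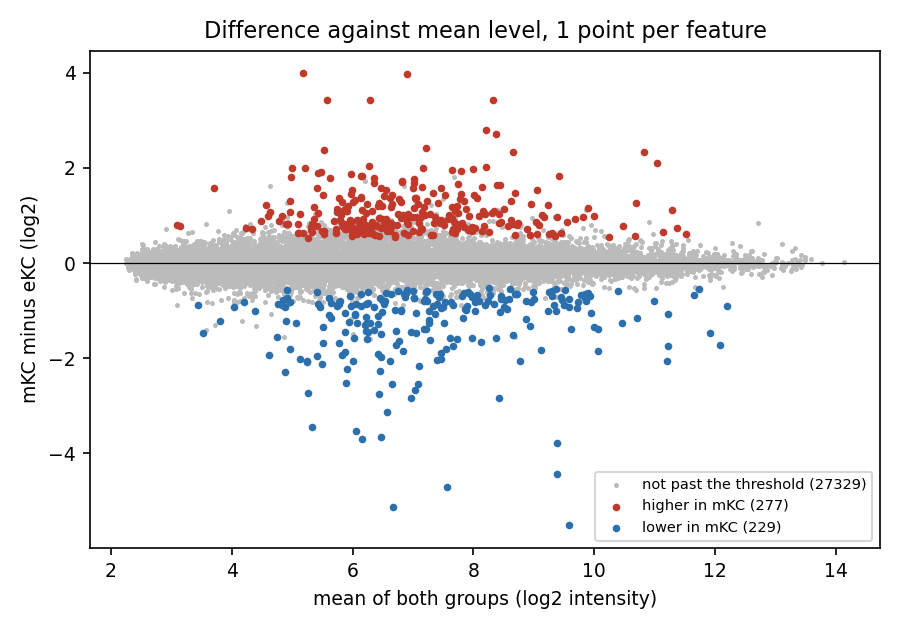
Difference between mKC and eKC (log2, vertical axis) against the mean of both groups (log2 intensity, horizontal axis), with 1 point for each of the 27835 features. The 277 features higher in mKC are red, the 229 lower are blue and the rest are grey; falls reach -5.51 and rises 3.99.

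The largest measured fall, by the mean of 3 animals, was in ENSMUSG00000055546. It dropped from 12.34 ± 0.0509 in eKC to 6.83 ± 0.239 in mKC (log2, SD, n = 3). Its difference was -5.51 ± 0.114 (SE), or 45.7-fold, with an adjusted p of 7.1e-05 in limma, and it lay between -5.77 and -5.36 in the 3 animals. In eKC this feature was above the 99th percentile of its arrays, which lay between 11.68 and 11.74. ENSMUSG00000051906 fell by 5.14 ± 0.183 (SE), or 35.3-fold, from 9.25 ± 0.258 to 4.11 ± 0.325 (limma, adjusted p = 0.00024). Its fall was the larger of these 2 in animal 1 (-5.70 against -5.36) and the smaller in animals 2 and 3. Its mKC level was not shown to be above background, so its fold and the order of the 2 falls are uncertain. The largest measured rise was in ENSMUSG00000094335, from 3.18 ± 0.446 in eKC to 7.17 ± 0.482 in mKC. That is 3.99 ± 0.313 (SE) or 15.9-fold (limma, adjusted p = 0.0030), and the difference ranged from 3.25 to 5.01 between animals. Its eKC level lay among the lowest levels of the table, below 4.01, and was not shown to be above background, so its fold and its rank are uncertain. ENSMUSG00000030117 rose by 3.97 ± 0.221 (SE), or 15.6-fold, from 4.91 ± 0.489 to 8.88 ± 0.127 (limma, adjusted p = 0.0010). Each of these 4 differences was larger than the spread between animals, which the choice by threshold and size favours. Each had the same sign in 3 of 3 animals, which the choice required. The eKC level of both rises and the mKC level of ENSMUSG00000051906 lay under the median of all feature means, 5.24. RMA can compress intensities there, so these folds may be understated, but compression was not measured.

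**Figure D3:**
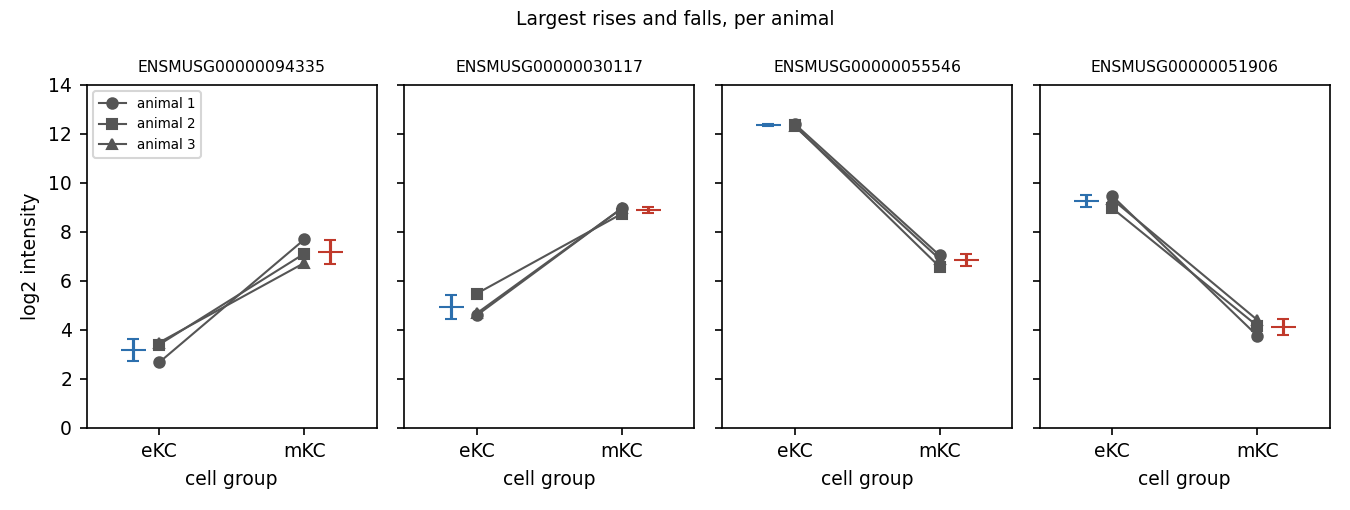
Log2 intensity (vertical axis) of the 2 features with the largest rise and the 2 with the largest fall in mKC, for eKC and mKC (horizontal axis); each grey line joins the samples of 1 animal, and the coloured marks give the mean ± SD of 3 animals. The lines of all 3 animals run the same way in every panel, which the choice of these features required.

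Called features were concentrated among those of moderate and high intensity, by the mean of both groups. A feature low in either group is lifted in this ranking by a high level in the other, which favours this pattern among called features. With the features ranked by mean level and cut into 4 bins of equal size, 6 (0.0862%) were called in the lowest bin, below 4.01, and 38 (0.546%) in the next, up to 5.24. Between 5.24 and 7.41, 265 (3.81%) were called, with 156 higher and 109 lower in mKC. Above 7.41, 197 (2.83%) were called, with 98 higher and 99 lower. Both group means lay above the median level of 5.24 for 226 of the 277 features higher in mKC and for 178 of the 229 lower. For 51 features higher in mKC the eKC mean lay below it, and for 51 lower in mKC the mKC mean did. The low counts in the dim bins do not show that dim genes were unchanged, since a compression of low intensities could also shrink their differences. That was not measured here.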

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

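The numbers of features past the threshold (506 in all, 277 higher and 229 lower in mKC) stayed within a factor of 1.5 under 9 alternatives. Without the replicate block, so that the arrays were no longer paired by animal, 608 features passed, of which 441 were among the 506. With the animal as a random effect (consensus correlation -0.0368) 546 passed. Quantile normalization gave 473, median centring 631, leaving out the lowest 30% or 50% of features 574 or 583, an intensity trend with robust estimation 705, and array weights 588. An adjusted p under 0.1 gave 745. Leaving out 1 animal, which leaves 1 residual degree of freedom, gave 171 to 369 in all, 78 to 233 higher and 93 to 136 lower. The total fell by over 1.5 times without animal 1 (252) and without animal 3 (171), and of these 234 and 158 were among the 506. A log2 difference of at least 1 in addition to the threshold left, by construction, fewer: 236 in all, 123 higher and 113 lower. An unadjusted p under 0.01 with that difference, which is looser on p, gave 258, 137 and 121. The 4 features given by identifier kept their direction and passed the threshold in all 43 tests, each of 1 feature under 1 alternative, with limma adjusted p-values from 5.9e-07 to 0.020. They were chosen from the same arrays for their large differences, and several alternatives leave the difference itself unchanged. Keeping the direction was therefore to be expected and is no independent support. ENSMUSG00000094335 was not tested with the lowest 50% of features left out. A mean of several probe sets per gene and a test of every row as its own feature, both foreseen, would change nothing because each gene had 1 row, and none was run for the gene lists or the genes of the sort, which had no symbols. Intensity limits these results: the table gives no signal over background, so no feature could be called detected or not.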

Other observations

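The tests on carried-over cells were chosen after the differences were seen, and their rule was revised more than once with the counts in view; the other tests were written down before their own results were seen.

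Of the 10 ways to split the 6 arrays into 3 and 3, the real split was the only 1 with calls at the threshold. It gave 506, 277 higher and 229 lower, and the highest of the other splits gave 0, including the 3 others that part every pair of an animal. With 10 splits a share under 0.05 is out of reach for the total and for each direction. In each of the other splits, differences between mKC and eKC enter the residual and raise it. Few calls were therefore to be expected there, so the contrast with the real split does not decide whether its calls arose by chance.

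Of the called features, 270 of 506 (53.4%) differed by less than 2-fold, a share that also depends on which differences the fit could detect. Cells of one population carried over into the sort of the other could shrink differences, but no feature can then lie below the carried-over share. The lowest mKC level among called features was 2.43% of the eKC level and the lowest eKC level 10.5% of the mKC level, each in the highest of the 3 animals, which are upper limits on such shares if intensity is proportional to RNA. With these limits removed, 260 of the 270 differences (96.3%) stayed under 2-fold for eKC in the mKC sort, 219 (81.1%) for mKC in the eKC sort and 198 (73.3%) for both together. With the same limits removed in single animals, 184 to 233 stayed. The bar, set with the counts in view, was that fewer than 10% would stay if carry-over were the whole cause. Removing shares this small moves only differences already near 2-fold past it. Missing the bar was therefore to be expected, and it does not test the cause. The counts show only that removing shares up to these limits left most of the 270 differences under 2-fold, as far as intensity is proportional to RNA. Carry-over stays open for the 10, 51 and 72 differences that passed 2-fold, and for whether differences under 2-fold were the majority, since those left were 51.4%, 43.3% and 39.1% of the 506. A true small difference between origins also stays open and was not tested.

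At a log2 difference of at least 2, 32 called features were lower in mKC and 15 higher. Lower features outnumbered higher ones in all 11 refits with another setting, from 26 higher against 31 lower without animal 2 to 14 against 34 without animal 1. The refits reuse the same arrays, and several leave every difference unchanged. Their count is therefore no independent support for the imbalance, which was not tested. Within animals 1, 2 and 3 singly, 30, 21 and 20 features were higher by at least 2, and 30, 38 and 36 lower. Limits of the array scale could hold rises down, and neither end was excluded. The 15 largest rises had a median mKC level of 8.88, against a 99th percentile of all values of 11.7, and their median eKC level was above the median mKC level of the 15 largest falls by 0.945 with a bootstrap SE of 0.960. By the rules written beforehand, both comparisons came out on the side against a limit, the first by more than the SD of 1.78 of those mKC levels. The bootstrap SE was no part of those rules. That outcome is not used, because both comparisons ran on features chosen for the size of their difference. A feature held down by a limit would not appear among them, so the comparisons decide nothing. A difference that follows from cell origin itself was not tested.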
